A study of Phaeodactylum tricornutum with 3 samples.

How the data were processed

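H3K4me3 was measured by chromatin immunoprecipitation and sequencing in formaldehyde-crosslinked cells of Phaeodactylum tricornutum, with 2 H3K4me3 libraries and 1 input library, sequenced as single reads of 50 bp per the labels' protocols. FastQC, Trimmomatic, MACS2, deepTools and SAMtools are named per the submitters' processing notes, with no version, role or order. The aligner, the caller that made the list, its settings, the genome build and whether the 2 libraries were pooled are not given in the sources used here. The file analysed was 1 peak list for the whole series, without a header, so the meaning of its columns was read from their values.

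The authors' deposited list gives for each peak a start and an end in bp, a column with values on a log10 scale between -98.1 and -1.33 that behaves like the log10 of a p-value, and a ratio or fold enrichment with a median of 1.93. Other deposited columns, of another unit, are 2 positions in bp inside each peak, called here the first and second inner position. Fold enrichment and log10 value are the authors' own per peak, and were used to describe, rank and filter peaks within this list. Fold was also tested by permutation between gene lists, between contigs and chromosomes, and against peak width. Those tests rest on the reading of that column from its values. The total depth is unknown, so no interval or limit from read counts is given. Exact binomial intervals and tests across genes treat genes as units, cover counting error only and say nothing about the spread between cultures, and the labels do not say whether the 2 libraries came from separate cultures.

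Gene positions and symbols came from the NCBI gene table of assembly ASM15095v2, with 10398 genes, 724 of them with a symbol. Of these genes, 10022 lay on chromosomes 1 to 33 and 376 on unplaced sequences whose names do not pair with the contig names of the peak list, so the contigs entered no gene comparison. Because the list names no build, its match to the table was tested on the values. The first inner position of narrow peaks lay in a gene for 74.4% at the listed coordinates, and for between 46.8% and 66.4% after moving them by 12 distances of 200 to 20000 bp either way, lowest at 500 bp and highest at 2000 bp. The drop for narrow peaks was largest at -500 and 500 bp. For the first inner positions of peaks of all widths, the unshifted share was above those at both distances in 33 of 33 chromosomes. No coordinate of the gene table is printed.

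The gene table has no strand, exons or product names. The tests of gene starts, peak position along the strand, gene arrangement, intron number and genomic classes that were planned before the data were examined could therefore not be run. In their place a gene counted as carrying a peak when at least 1 bp of it was overlapped, an alternative planned before the data were examined, and windows of 500 bp were set at both ends of each gene. The overlap of replicate peak sets could not be computed from 1 list. The planned gene lists rested on product names and were replaced by 30 lists defined by gene symbol, with functions read from the symbols alone, written after the file was seen and before any peak was compared with a gene. The limits of 1000 and 10000 bp for narrow and wide peaks and the analysis of the inner positions were also chosen after seeing the data, except that a peak summit, for which the first inner position was used, was planned for peaks near gene ends and for the share of genes with a peak.

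Overlaps with genes were tested against 1000 circular shifts of the peaks within each chromosome, which keep peak widths and spacing (two-sided permutation tests). Gene lists with at least 5 genes were tested with Fisher's exact test against all other genes, and the median fold of a list was tested against 100000 random draws from the genes with a peak, both with Benjamini-Hochberg adjustment over the lists. Chromosomes were compared with 10000 shuffles. Named genes were the 10 with a symbol and the highest fold, the longest 5 with a symbol and no peak within 1000 bp, the genes of the 5 widest peaks, and members of lists that passed the adjusted test, of which there were none. Alternatives included windows of 250 and 1000 bp, the stronger part of the list by either value, peaks of at least 200 bp, joining of peaks within 200 bp, random placement and other definitions of a gene with a peak.

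The shift test was tested on simulated data, with 882 narrow peaks per simulation. It called 0 of 20 simulations with random peaks and 20 of 20 in which about 50% of the peaks were set at gene ends. For the gene lists, Fisher's exact test with adjustment was simulated over 10022 genes, with 95% of the genes of changed lists carrying a peak. It called 26.0% of 200 changed lists, 56.3% of the 64 changed lists with 20 or more genes, and 1 of 400 unchanged lists. Over all sizes most changed lists were missed. Genes were drawn independently, without peaks shared by neighbours, and several lists were changed at once, so these rates may not hold for the real lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.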

Results

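Trimethylation of lysine 4 of histone H3 (H3K4me3), a chromatin mark found at active gene starts in many eukaryotes, was mapped in the marine diatom Phaeodactylum tricornutum, strain Pt1 8.6, by chromatin immunoprecipitation and sequencing. The series held 2 H3K4me3 libraries and 1 input library of wild-type cells in normal growth. The values analysed were those of 1 list of 2168 peaks for the whole series, so no value below has an error between replicates. Of these peaks, 2083 lay on chromosomes 1 to 33 and 85 on 20 unplaced contigs. Read counts are not given in the sources used here and the depth is unknown. The genome build of the peak positions is not given either, and they are printed as the authors' list gives them.

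The first question was how much of the genome carried H3K4me3. Peaks covered 45.5% of the 25931 kb spanned by chromosomes 1 to 33. The largest part of that came from 406 wide domains of over 10000 bp, which covered 31.2% of the span and often ran across many neighbouring genes. Narrow peaks of under 1000 bp were more numerous, at 882, and covered 1.92%. Neighbouring enriched pieces may have been joined during peak calling, so the covered bases may include unmarked stretches. The widest domain lay on chromosome 11 from 433639 to 498932, measured 65293 bp and overlapped 32 annotated genes, among them the UDP-galactose epimerase gene GALE1 and the nucleotide transporter gene NTT4.

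The next widest domains lay on chromosome 23 from 85772 to 147162, with 26 genes including FAO1, and on chromosome 8 from 222158 to 281448, with 29 genes including hUbi and PAS. The domain on chromosome 12 from 113478 to 170000 overlapped 31 genes, none of them with a symbol. The domain on chromosome 1 from 827877 to 881862 overlapped 30 genes, including RFC4, a subunit of the replication clamp loader. These 5 domains had fold enrichments between 1.17 and 1.43 in the authors' list. Their log10 values, from the widest down, were -5.21, -19.9, -2.11, -17.0 and -1.67. All were weaker than the median of -23.5 for the wide domains, and the weakest value in the list was -1.33.

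By fold, wide domains were weakly enriched and narrow peaks more strongly. The median fold enrichment was 2.49 for the narrow peaks, 1.74 for the 795 peaks of intermediate width and 1.36 for the wide domains. By log10 value the narrow peaks were the weaker ones, with a median of -14.2. The peaks of intermediate width and the wide domains both had a median of -23.5. Across the 2083 peaks, which are not independent replicates, width and fold enrichment had a Spearman rho of -0.735 with a permutation p of 0.0001, the smallest the shuffles can give. Peak width had a median of 1648 bp with quartiles at 617 and 7356 bp. The 848 peaks that overlapped 1 gene had a median fold of 2.43, while the 150 peaks with 11 or more genes had a median of 1.32 and held 37.6% of all peak bases. Peaks outside annotated genes numbered 169. The coverage depends on which peaks are kept: the stronger part of the list covered 3.98% of the span when split at the median fold, which falls with width, and 26.1% when split at the median log10 value.

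**Figure D1:**
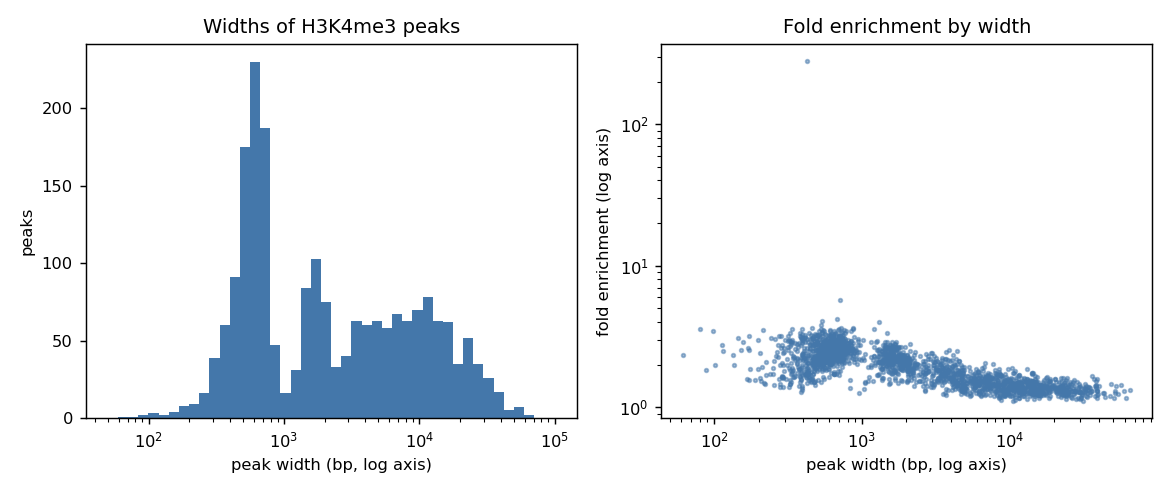
Left, the number of H3K4me3 peaks on chromosomes 1 to 33 by peak width in bp on a log axis; right, each peak's fold enrichment (a ratio, log axis) by its width. The narrow peaks have a median fold of 2.49 and the peaks over 10000 bp a median of 1.36, with a single point at a fold of 280.

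**Figure D2:**
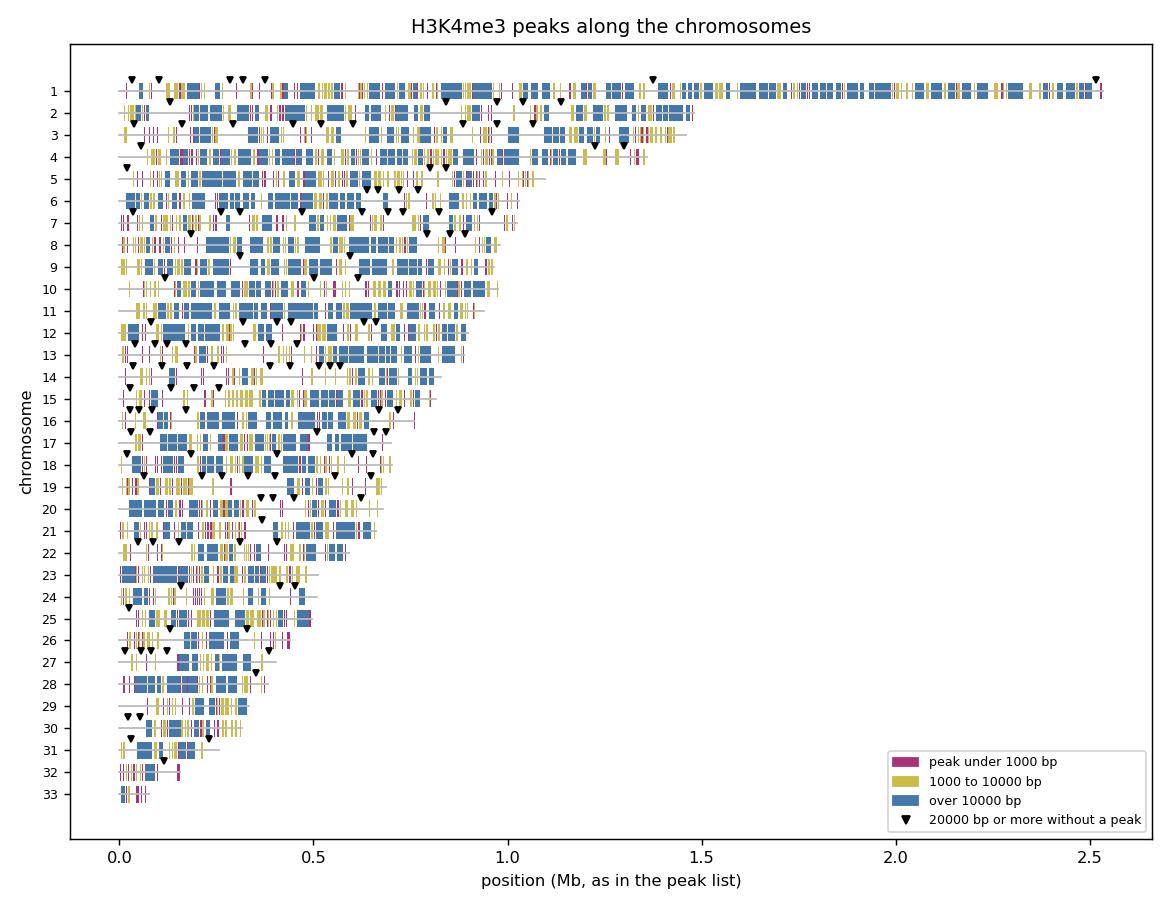
Positions of the 2083 H3K4me3 peaks along chromosomes 1 to 33 in Mb, coloured by peak width, with peaks drawn at least 1500 bp wide so that they are visible. Triangles mark the 125 stretches of 20000 bp or more without a peak.

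The second question was whether H3K4me3 lay on genes and where within them. Of 10022 annotated genes on the chromosomes, 7064 (70.5%) overlapped a peak, compared with 58.0% ± 0.390 (SD over 1000 shifts) when the peaks were moved along their chromosomes (permutation test, two-sided, p = 0.001, the smallest 1000 shifts can give). Genes covered by peaks over their whole length numbered 4701 (46.9%), a count that may include unmarked stretches inside joined peaks. Of the 707 genes with a symbol, 518 (73.3%, 95% exact binomial interval 69.8 to 76.5) had a peak, against 70.3% of the genes without a symbol (Fisher's exact test, two-sided, p = 0.0954). For 88.2% of the genes with a peak, the peak of highest fold also overlapped another gene. Among genes without the end of another gene within 1000 bp, 48.4% had a peak, and no shifted value was computed for them. The share of all genes with a peak was 11.6% (10.1% shifted) with the stronger part of the list by fold and 39.9% (32.7% shifted) by log10 value. Narrow peaks on their own overlapped 7.33% of the genes, against 7.15% after shifting (permutation test, two-sided, p = 0.204). The share of narrow peaks that lay in genes, given below, is a different measure. By bases the excess of all peaks was smaller, with 65.6% in genes against 63.4% after shifting. Wide domains held 4.70 genes per 10 kb, against 3.91 for shifted domains, so the excess in the gene count may partly reflect gene-dense stretches.

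The most strongly enriched named genes by fold, which falls with peak width, each carried a narrow peak that overlapped no other gene. GapC2a and GapC2b, which encode glyceraldehyde-3-phosphate dehydrogenases of glycolysis, stood first, with fold enrichments of 3.62 at 704677 to 705136 and 3.29 at 730218 to 730698 on chromosome 16. Their names mark them as copies, and whether reads were shared between them was not tested, so their separate values are uncertain. By log10 value both peaks were weaker than the median peak on the chromosomes, at -11.3 and -11.9 against -19.1. The peaks of the other genes named here were stronger than that median. Sec7C, grouped here with the vesicle coat genes, followed at 3.29 on chromosome 32 from 96906 to 97576. BGER1 on chromosome 1 (451796 to 452423) and GltX on chromosome 22 (581267 to 581729), both had 3.09. SQD1, of sulfolipid synthesis, had 3.08 on chromosome 11 from 858366 to 858767. The chaperone gene Hsp70_2 on chromosome 13 (258649 to 259451) and the phosphoglycerate mutase gene PGAM_3 on chromosome 3 (97108 to 97732) both had 3.0. HemD, of tetrapyrrole synthesis, had 2.93 on chromosome 4 from 1036884 to 1037524, and D-LCR had 2.86 on chromosome 8 from 151384 to 151880. In Sec7C the peak covered 7.39% of the gene, in GltX 9.13% and in HemD 64.6%.

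At the other extreme, 2244 genes (22.4%), 153 of them with a symbol, had no peak in the gene or within 1000 bp. The 5 longest of these with a symbol were TRD5 on chromosome 26, the meiotic helicase gene MER3 on chromosome 21, ETR1 on chromosome 7, GAPN on chromosome 6 and NRPS on chromosome 12, with lengths of 7814, 5664, 5164, 4695 and 4209 bp.

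By their first inner position, narrow peaks sat just inside an end of a gene more often than shifted peaks, though not all of them did. The authors' list gives 2 inner positions per peak, and the first of them lay inside a gene for 74.4% of the narrow peaks, against 62.8% ± 1.66 (SD over 1000 shifts) by chance (permutation test, two-sided, p = 0.001). The median distance of such a position to the nearest gene end was 230 bp inside the gene (quartiles 153 and 346 bp), compared with 441 bp for shifted peaks (permutation test, two-sided, p = 0.001). Positions within 300 bp inside a gene end made up 49.1% of the narrow peaks and 22.4% of the shifted ones. In genes of at least 2000 bp, 94.4% of 287 such positions fell in one of the outer parts when the gene was divided into 3 equal parts, against 66.8% after shifting (permutation test, two-sided, p = 0.001). The gene table used here has no strand, so starts and ends of genes were not told apart.

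Wide domains showed the same placement of their first inner position. It lay within 300 bp inside a gene end for 54.7% of the wide domains, against 22.7% of the shifted ones (permutation test, two-sided, p = 0.001). The second inner position of the wide domains lay in a gene for 59.1%, against 63.7% after shifting (permutation test, two-sided, p = 0.0519), and for 52.3% of all peaks over 2000 bp, against 63.3% (permutation test, two-sided, p = 0.001). In narrow peaks the second inner position lay in a gene for 74.5%, against 62.8% after shifting (permutation test, two-sided, p = 0.001). Among all peaks it lay inside the window at a gene end for 75.3%, against 57.0% after shifting (permutation test, two-sided, p = 0.001). What the 2 positions stand for is not given in the sources used here.

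**Figure D3:**
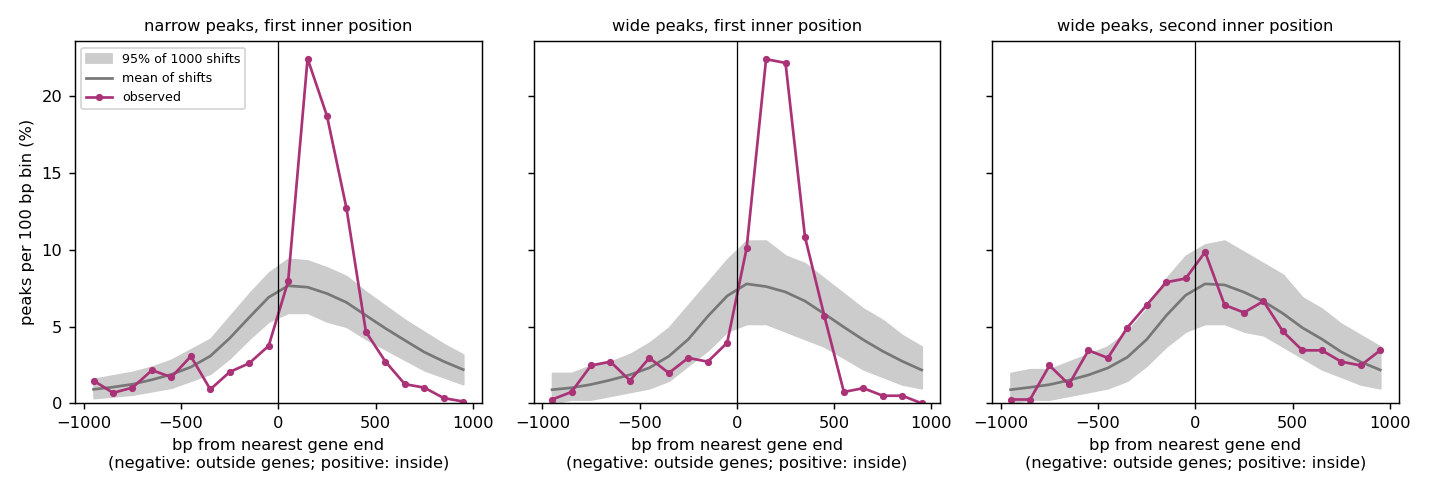
Share of peaks (percent per 100 bp bin) by the distance in bp of an inner position of the peak from the nearest gene end, negative outside genes and positive inside, for narrow peaks and peaks over 10000 bp; the grey line and band are the mean and 95% range of 1000 circular shifts. The first inner positions peak inside genes, with 49.1% of narrow peaks and 54.7% of wide peaks within 300 bp inside a gene end, and the second inner positions of wide peaks, with 22.2% against 22.8% for shifted peaks, show no such excess.

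Near gene ends as a whole, 94.0% of the peaks overlapped a window of 500 bp either side of an annotated end, against 85.9% of shifted peaks (permutation test, two-sided, p = 0.001). Of all peak bases, 65.6% lay in genes, against 63.4% after shifting (permutation test, two-sided, p = 0.001), in a genome of which 63.1% is annotated as genes. The excess was larger for narrow peaks, with 71.7% against 62.8% (permutation test, two-sided, p = 0.001).

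The third question was whether groups of genes differed in H3K4me3. Enzymes of carotenoid and isoprenoid synthesis had the highest share among the larger lists, with a peak in 22 of 24 genes (91.7%), and pyruvate dehydrogenase, citric acid cycle and glycine cleavage genes came next with 20 of 22 (90.9%). All 6 genes of the SMC chromosome structure proteins had a peak. The lowest shares were those of the Lhcf light harvesting proteins, the main antenna of diatoms, with 9 of 17 (52.9%), and of the histones, with 7 of 13 (53.8%). None of the 30 lists passed Fisher's exact test (two-sided) after Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05.

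Those 2 were carotenoid and isoprenoid synthesis (Fisher's exact test p = 0.0232, adjusted p = 0.527) and pyruvate dehydrogenase with the citric acid cycle (Fisher's exact test p = 0.0351, adjusted p = 0.527). Fisher's test treats genes as independent. Under circular shifts, which keep the spacing of peaks, their unadjusted p was 0.125 and 0.0749 (permutation test), and 0 lists fell under 0.05. In the first list, the zeaxanthin epoxidase gene ZEP1 and VDL2 shared a peak of fold 2.0 on chromosome 8 from 451487 to 453768, and HDS had a peak to itself with fold 1.78. PSY, PDS1, PDS2, ZDS and the violaxanthin de-epoxidase gene VDE also had peaks, while LCYB and CRTISO1 had none. In the second list, OGD1 had the highest fold at 2.68, the pyruvate dehydrogenase gene PDHA1 had 1.67, and PDH1 and SHMT had no peak. Names of list members outside the fixed rule for named genes were chosen after their values were seen.

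Among light harvesting genes, Lhcf5 and Lhcf11 shared a domain of 14152 bp with fold 1.73 on chromosome 24, and Lhcf12 and Lhcf17 shared 1 of 37978 bp with fold 1.42 on chromosome 25. Lhcf1, Lhcf2, Lhcf3, Lhcf4, Lhcf6, Lhcf7, Lhcf15 and Lhcf16 had no peak (Fisher's exact test for the list, p = 0.118, adjusted p = 0.775). The Lhcr genes had a peak in 8 of 14, with the highest fold, 2.76, in Lhcr10. Among the histone genes, H2A-3a, H2A-3b and H2B-1b lay in 1 domain of 38541 bp on chromosome 6 with fold 1.36, H3.3 had fold 1.55, and H1, H2B-1a, H3-1a, H3-1b, H4-1a and H4-1b had no peak (Fisher's exact test for the list, p = 0.224, adjusted p = 0.775). Lhcf1, Lhcf2, Lhcf3 and Lhcf4 lay in 1 stretch without a peak, and H1, H3-1a, H3-1b, H4-1a and H4-1b in 1 other, so these absences are not separate events. Under circular shifts the unadjusted p was 0.561 for the Lhcf list and 0.355 for the histones (permutation test). Both are multigene families, and whether reads were shared between copies was not tested, so the calls for single members are uncertain.

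The other lists lay between these. Vesicle coats and SNAREs had a peak in 29 of 35 genes, cyclins in 18 of 22, ER-associated degradation and plastid translocon genes in 16 of 19, and heat shock proteins in 14 of 17. Tetrapyrrole synthesis had 13 of 16, or 12 of 15 without GltX, whose place in it is uncertain, plastid and nucleotide transporters 16 of 20, thioredoxins and antioxidant enzymes 14 of 18, and Calvin cycle and pentose phosphate enzymes 7 of 9, with Prk and SBPase lacking a peak. The iron uptake and silicon transport list had 12 of 16, the COP9 signalosome 6 of 8, ubiquitin and SUMO components 14 of 19, small GTPases 15 of 21, fatty acid and lipid synthesis 22 of 31, and DNA repair 12 of 17. Shares under the 70.5% of all genes were found for the anaphase promoting complex (9 of 13), plastid electron transport (6 of 9), cytoskeleton and motors (19 of 30), Lhcx and one-helix proteins (5 of 8), DNA replication (9 of 15) and a mixed list of photolyases, heat shock factors, E2F/DP and other genes (9 of 15, of which the photolyases and heat shock factors had 4 of 7). Cyclin dependent kinases had 7 of 12, P-type and other ATPases 5 of 9 and the RPN proteasome subunits 6 of 11. With windows of 1000 bp at the gene ends, all 13 anaphase promoting complex genes had a peak, against 77.5% of other genes.

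**Figure D4:**
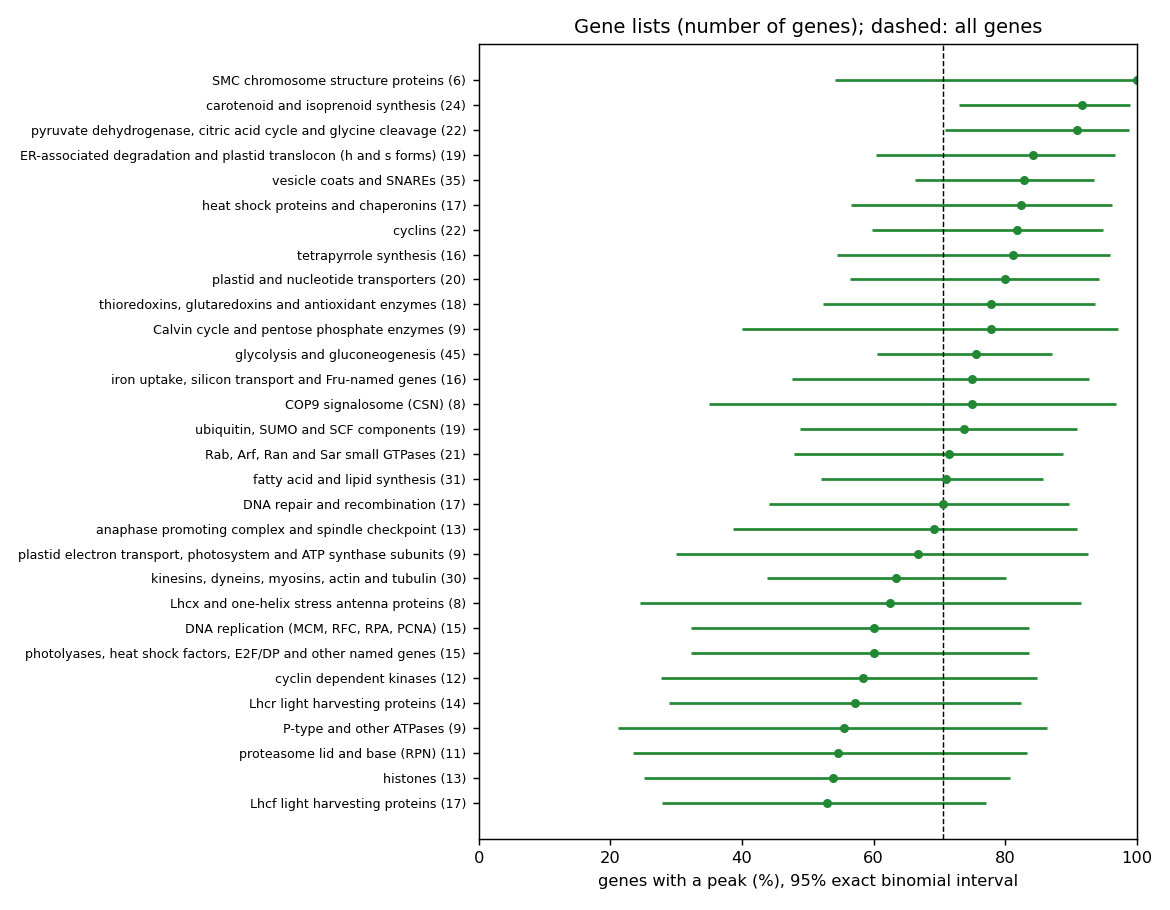
Share of genes with an H3K4me3 peak (percent) in each of 30 gene lists, with the number of genes in parentheses; points are the observed shares, bars their 95% exact binomial intervals and the dashed line the 70.5% of all genes. The shares run from 52.9% for the Lhcf proteins to all 6 SMC genes, and no list passed the adjusted test.

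Glycolysis and gluconeogenesis had a peak in 34 of 45 genes (75.6%). The median fold of those 34 was 1.60, against 1.42 for all genes with a peak, with the lowest p of the lists (permutation test, two-sided, p = 0.00402, adjusted p = 0.121). Beside GapC2a, GapC2b and PGAM_3, the pyruvate kinase genes PK3, PK1 and PK4b had folds of 2.86, 2.83 and 2.74, each in a peak that overlapped no other gene. GAPN, PEPCK1, Fba4, FBPC2 and FBPC3 had no peak. No list passed the permutation test of fold after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05. Neighbouring genes share peaks, so the genes of a list are not independent.

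The share of genes with a peak rose less with gene length than it did for shifted peaks, and the share covered over at least 50% fell more. A peak was present in 65.9% of the genes of the shortest of 5 length classes (95% exact binomial interval 63.8 to 68.0) and in 73.8% of those of the longest (71.8 to 75.7). Coverage of at least 50% of the gene fell from 63.1% of the shortest to 26.7% of the longest genes. Across genes, which are not independent replicates, length and presence of a peak had a Spearman rho of 0.0584, below the mean of 0.127 for shifted peaks (permutation test, two-sided, p = 0.001), so the rise was smaller than for shifted peaks. Length and coverage of at least 50% had a rho of -0.260, against a mean of -0.0205 for shifted peaks (permutation test, two-sided, p = 0.001).

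The share of genes with H3K4me3 ranged widely over the chromosomes. Chromosome 11 had the highest share, 89.6% of 367 genes (95% exact binomial interval 86.1 to 92.6), followed by chromosome 23 with 85.9% of 192. Chromosome 19 had the lowest, 41.1% of 258 genes (35.0 to 47.4), followed by chromosome 14 with 47.2% of 316. Peaks covered 63.9% of chromosome 11 and 25.9% of chromosome 19. The chi-square statistic over the 33 chromosomes was 594 (permutation test with 10000 shuffles of genes, p = 0.0001, the smallest they can give). Neighbouring genes shared their state, and when the marks were moved together along the gene order the statistic had a mean of 580 and the observed value was not exceptional (permutation test, p = 0.424).

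**Figure D5:**
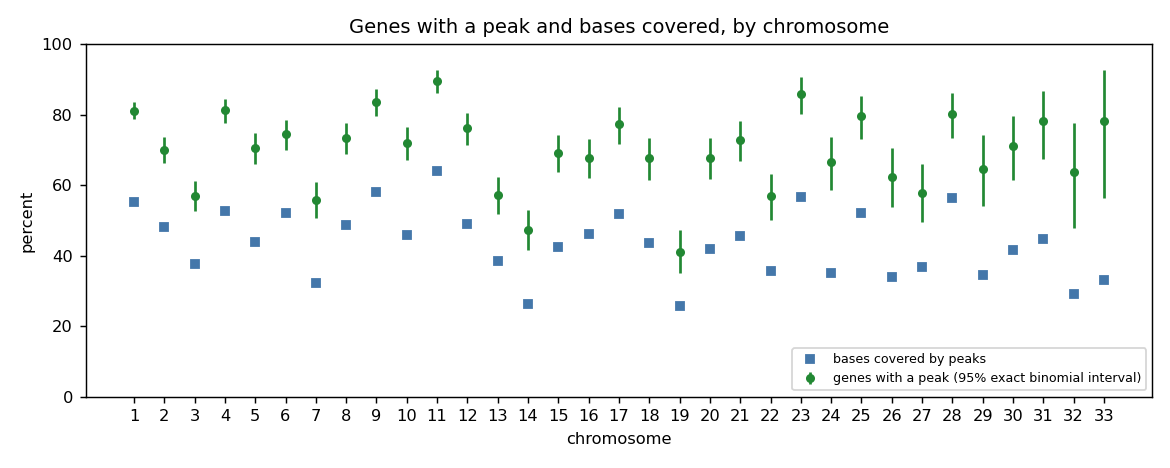
Share of genes with an H3K4me3 peak (green points, percent, with 95% exact binomial intervals) and share of bases covered by peaks (blue squares, percent) for each of the 33 chromosomes. Chromosome 11 is highest on both measures (89.6% and 63.9%) and chromosome 19 lowest (41.1% and 25.9%).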

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

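Peaks on the unplaced contigs, 85 in number on 20 contigs, stood out as signal in data that the gene comparisons did not use. Their median fold enrichment was 2.28 against 1.92 for the chromosomes (permutation test, two-sided, p = 0.0012). Their highest values lay on bd_33x35, where 2 peaks had folds of 6.08 (32047 to 32599) and 6.02 (27338 to 27825). The contig with the most peaks, bd_32x35 with 27, had a median of 1.86, below that of the chromosomes. The medians of bd_10x23, bd_27x34 and bd_28x34 were also below it, at 1.68, 1.69 and 1.14, and those of the other contigs above it. Fold was higher in narrow peaks, but a larger share of narrow peaks on the contigs is argued against as the whole cause: among peaks under 1000 bp the contig median was still higher by 0.458, at 2.94 against 2.49 (permutation test, two-sided, p = 0.0001, the smallest the shuffles can give). For the peaks under 1000 bp, a few contigs with many peaks are argued against too, since with 1 median per sequence, the difference was 0.867 over the 14 contigs with such peaks and 33 chromosomes (permutation test, two-sided, p = 0.0002). Repeated sequence with few reads in the input may also raise the ratio and stays open, since no read count was analysed here, and no biological explanation was tested.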

How the results depend on the processing

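Alternatives added after seeing the data are those on the log10 value, on the inner positions (except the first for peaks near gene ends and for the share of genes with a peak), on narrow, wide or all peaks as a class, on coverage of at least 50% of a gene, on genes with a peak to themselves, on list members of doubtful function and on marks moved along the gene order. The share of peaks near a gene end kept its direction and its side of the threshold in all 9 alternatives run, and the share of genes with a peak in 9 of 10. The share itself, 70.5%, was 11.6% (10.1% shifted) for the stronger part of the list by fold and 39.9% (32.7%) by log10 value. The exception was narrow peaks only, with 7.33% of genes (permutation test, p = 0.204). Coverage of the chromosomes, 45.5% in full, was 3.98% for the stronger part of the list by fold and 26.1% by log10 value, since fewer peaks were left and fold fell with width. No gap was under 200 bp, so joining peaks within that distance tested nothing. The share of narrow peaks with the first inner position in a gene kept its call in all 5 alternatives run and the share of peak bases in genes in both. The second inner position lay in genes for 52.3% of peaks over 2000 bp, past the threshold that the 59.1% of the wide domains missed (the cause was not tested). Under the 9 alternatives that tested all 30 lists 0 passed, with lowest adjusted exact or permutation p between 0.268 and 0.963. Leaving out genes with another gene within 1000 bp left 1 list to test. For fold, 1 list passed when only genes with a peak to themselves were kept: glycolysis, with 9 genes, a median of 2.83 against 2.44 and an adjusted permutation p of 0.0493, but it was the only list with 5 such genes, so nothing was left to adjust for. The rho with gene length, 0.0584, turned to -0.260 for coverage of at least 50% of the gene and was 0.197 for a first inner position in the gene. Each lay below its mean for shifted peaks, 0.127, -0.0205 and 0.219 (the cause was not tested). The chi-square statistic of 594 over chromosomes no longer passed when marks were moved along the gene order (permutation test, p = 0.424). No paired analysis was possible because the list does not separate the 2 libraries, and leaving out a replicate, replicate overlap and the strand-based alternatives could not be run for want of values per library and strand. Depth is unknown and what it limits cannot be stated.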

Other observations

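The tests of closely packed genes, of joined peaks and of the longest stretch were chosen after the result was seen. The names in the stretches without peaks were chosen after their values were seen, outside the rule for named genes. No peak was listed in long continuous stretches that hold well-known genes. The longest stretch without a peak, on chromosome 2 from 81060 to 180533, measured 99473 bp and held 44 genes, including the antenna genes Lhcf1, Lhcf2, Lhcf3 and Lhcf4. On chromosome 6, a stretch from 748907 to 789993 held 22 genes, including the linker histone gene H1, H3-1a, H3-1b, H4-1a, H4-1b and the cyclin gene dsCYC2. A stretch on chromosome 1 from 82721 to 121169 held Fba4, SBPase, FBPC2, FBPC3 and ACPZ, of carbon and lipid metabolism, and 1 on chromosome 2 from 803051 to 880845 held hRad23, Ras1, NTT5, Lhcr3 and HSP40A. Genes in the same stretch are 1 event rather than separate ones.

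In all, 125 stretches of 20000 bp or more without a peak covered 4627 kb, 17.8% of the chromosomes, and held 1612 genes, 127 of them with a symbol. Few genes may explain a part of them: 58.6% of their bases lay in genes, against a mean of 62.9% for shifted stretches (permutation test, two-sided, p = 0.001). The longest stretch is not explained that way, since 63.02% of its bases lay in genes, against 63.1% of all chromosomes. Poor read mapping and a local loss of signal in either library stay open, because neither reads nor sequence were analysed here. No biological explanation was tested.

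The wide domains raise the question of whether they are single units. Domains over 10000 bp held 4.70 genes per 10 kb, against a mean of 3.91 for shifted domains (permutation test, two-sided, p = 0.001), so closely packed genes that each carry the mark are a candidate explanation for a part of them. Joining of neighbouring enriched pieces during peak calling is another: of 2050 gaps between neighbouring peaks, 0 were under 500 bp and the smallest measured 530 bp, against 152 gaps under 500 bp when the same peaks were placed at random without overlap (permutation test, two-sided, p = 0.001). Both may act together, and a continuous domain of marked nucleosomes stays open. No biological explanation was tested.

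The peak with the highest fold of the list lay on chromosome 15 from 9349 to 9775, in the gene PHATRDRAFT_47779. It had a fold of 280 and a log10 value of -29.2. The next highest fold on a chromosome was 5.76 at 244754 to 245464 on chromosome 30. Peaks of far lower fold had similar log10 values, such as BGER1 with 3.09 at -32.9 and Sec7C with 3.29 at -27.8. The log10 value thus does not bear out the fold of 280, which is uncertain, and its cause was not tested.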
